A study of Homo sapiens with 12 samples.

How the data were processed

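RNA sequencing libraries from AU565, an established human breast carcinoma line with an amplified ERBB2 gene, were analysed in 4 culture formats. The formats were monolayer, small spheroid, large spheroid and capsule, with 3 libraries each and 12 in all. Groups and replicate numbers come from the sample labels. Columns of the count table were matched to the labels by name, except that of capsule replicate 1, which spells the format differently and was assigned by format and number. Every library, monolayer included, carries the same treatment label: culture by liquid overlay with 5% matrigel after trastuzumab, an antibody against the ERBB2 receptor, with 96 h before RNA was taken. No library without the antibody was used here, so no comparison measures its effect. Cells were grown in RPMI with fetal bovine serum, RNA was extracted with TRIzol and libraries were made with a TruSeq kit, per the labels' protocols. The labels do not say whether the replicates of a format were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

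The authors deposited 1 table of whole-number read counts per Entrez gene for all 12 libraries. Reads were assigned to genes with featureCounts on build hg38, and limma was among the tools, per the submitters' processing notes. Alignment used subread, per the file headers. Tool versions, the annotation release, the strand setting and the filter on rows are not given in the sources used here. The deposited counts had 16020 rows, each above 0.5 CPM (counts scaled to library totals) in at least 2 libraries, the lowest second-highest CPM being 0.501. Rows without a gene symbol numbered 164 and held 0.0705% of all counts. They were kept in library sizes and, where they passed the filter, in the tests. Reads of near-identical copies (the MIR3648 copies, AKR1C1 and its relatives, ribosomal protein pseudogenes, metallothioneins) and of overlapping or antisense genes could be split or shared by the counting, so their values are uncertain. Gene positions were taken from the RefSeq table of assembly GRCh38.p14, which matched 15851 rows (98.9%) by Entrez identifier. They are 1-based positions of whole genes.

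Library totals ran from 13971346 to 24729250 counts. Pairs of replicates were compared by chi-square over 11701 genes with a mean count above 50. All 12 pairs differed by more than sampling noise. This does not show that the cultures were separate, and each library was treated as 1 sample.

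Counts were analysed in R 4.3.3 with edgeR 4.0.16. After filterByExpr with a minimum count of 10, 15175 genes were tested in 1 fit of all 12 libraries with 1 coefficient per format, TMM scaling and the quasi-likelihood F test. Benjamini-Hochberg adjustment was made over genes within each of the 6 pairwise comparisons, and a gene with adjusted p below 0.05 was called. Adjusted p-values of genes are from this test unless another is named. Levels are TMM-scaled CPM as mean ± SD over the 3 libraries of a format, and log2 fold changes carry their SE. Principal components used log2 CPM with a prior count of 2.

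Gene lists for 32 pathways, complexes and cell types were fixed with 650 tested members, 20 genes standing in more than 1 list. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the 32 lists of a comparison. The test was repeated with a correlation estimated from the data and with fry. Of the 62 calls at the preset correlation, 10 held with the estimated one, and fry called 137 of 192 list tests in 1 direction. Fry asks whether the genes of a list move on balance one way, without comparing them with other genes. For called lists, counts adjusted over the list alone are given beside those over all genes.

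The genes named in the text follow a fixed rule. Against monolayer, they are the 6 highest and 6 lowest log2 fold changes among called genes with a mean CPM of at least 10 in the higher format, no overlap between the libraries of the formats, and a symbol that is no clone name, pseudogene or bare identifier. To these come the 3 members with the smallest adjusted p of each called list among those moving its way. Between the other formats the numbers are 5, 5 and 2. The rule adds 16 genes in every comparison: ERBB2, ERBB3, EGFR, GRB7, MKI67, CA9, VEGFA, HMGCS1, FASN, CDKN1A, CDH1, VIM, FN1, IFIT1, TXNIP and KRT18. Not every gene the rule gives is named in the text. Other genes are said to have been chosen after their values were seen. Groups, the tests of the 6 comparisons, the 32 lists, this rule and the alternatives, except the correction named below, were set before the data were examined. Tests chosen later are named in the closing section.

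Where a format had 0 counts of a gene, the fold is a bound against 3 counts over the format's libraries. Where it had 1 to 3 counts, the ratio is given with its 95% Clopper-Pearson interval. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

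The alternatives were median-ratio (RLE) size factors, library totals without composition scaling, DESeq2 1.42.0, limma-voom, no filter, a CPM of at least 1 in at least 3 libraries, the replicate number as a block, counts thinned to the smallest total, removal of mitochondrially encoded and ribosomal protein genes, only the 2 formats compared, thresholds of 0.01 and of 2-fold, and each library left out in turn. DESeq2 gave no adjusted p for 3 genes in each comparison, and these stayed out of counts of lost calls. A correction for GC content and transcript length was added after seeing the data. It enters per-library spline trends (5 degrees of freedom each) of log2 CPM on the GC percent and length of each gene's longest GENCODE release 29 transcript as offsets. Values existed for 14638 tested genes (96.5%), and genes without one were left unchanged by the offsets. It is called the GC and length correction in the text.

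The fit was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. For small spheroid against monolayer it recovered 52 and 80 of them over 14525 genes, for large spheroid against monolayer 55 and 79 over 14520, and for capsule against monolayer 57 and 70 over 14517. For large against small spheroid it recovered 53 and 78 over 14518 genes, for capsule against small spheroid 58 and 75 over 14532, and for capsule against large spheroid 59 and 76 over 14511. False calls in that order were 12 (7.64%), 8 (5.1%), 5 (3.47%), 10 (6.29%), 5 (3.25%) and 5 (3.29%). In each simulated comparison the list test called the shifted list and none of 19 unshifted ones at adjusted p below 0.05. The simulated genes varied independently, few were changed and no GC trend was put in. These rates therefore need not hold for the real counts, and the list result does not test the correlation between genes. Because the 3 comparisons against monolayer share their controls, unchanged groups were simulated against those libraries in 20 draws. The formats were also regrouped: all 10 splits of the 6 libraries of each comparison, and 50 groupings of the 12 libraries. These 50 include the real one, and the others were drawn with a fixed seed. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.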

Results

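Gene expression was measured by RNA sequencing in 12 libraries of AU565 cells, a HER2-positive human breast carcinoma line, grown as monolayer, small spheroids, large spheroids or capsules (n = 3 each). The series title speaks of small spheroids and capsules, and the design compares expression between the formats. The monolayer libraries held 17216660, 24729250 and 21116229 counts and the small spheroid libraries 15709859, 14277546 and 13971346. The large spheroid libraries held 16962684, 19596772 and 17298633 counts and the capsule libraries 15742541, 14405091 and 14148600.

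Most genes differed between the culture formats: 13654 of 15175 genes (90%) passed the test among the 4 formats at adjusted p below 0.05, and 1521 did not pass. The first principal component took 46.3% of the variance and set small spheroid and capsule libraries against monolayer and large spheroid libraries. The titles of the libraries on that second side, and of no others, carry the letters UP, whose meaning is not given in the sources used here. The next components took 26.6% and 12.7%. Fold changes followed GC content across genes in several comparisons, with a Spearman rho of 0.614 between the 2 sides of the first component. Genes are not independent replicates, so no p is given for such values. Capsule replicate 1 stood apart from its partners, with a chi-square per gene of 39.1 and 34.6 against replicates 2 and 3, which differed by 2.99. Among the other formats this value ran from 2.8 to 12.6.

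**Figure D1:**
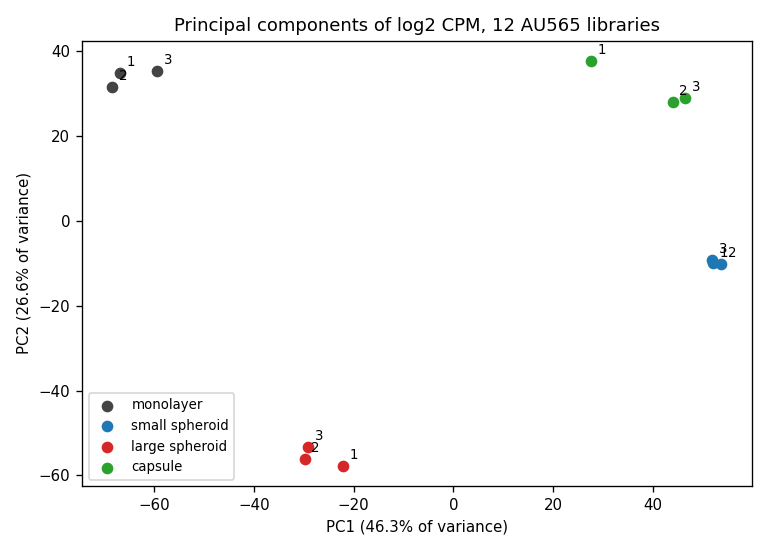
First and second principal components of log2 CPM for the 12 libraries, each point a library with its replicate number, coloured by format. The axes carry 46.3% and 26.6% of the variance, and small spheroid and capsule libraries lie on one side of the first axis with monolayer and large spheroid libraries on the other.

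Some genes known from other tissues were read unevenly across libraries. The cardiac myosin genes MYH6 and MYH7 stood at 72.14 and 87.65 CPM of the library total in monolayer 1 and at 69.67 and 90.1 in monolayer 2, against 0 and 0.0947 in monolayer 3. Large spheroid 1 and 2 held 17.39 and 17.71 CPM of MYH6, and large spheroid 3 held 0. The melanocyte gene TYRP1 stood at 26.95, 33.04 and 15.39 CPM in the monolayer libraries, and no higher than 0.143 in any small spheroid or capsule library. These genes were chosen after their values were seen.

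Small spheroids differed from monolayer by raised secretory luminal, hypoxia, glycolysis and immediate early genes (the last list a check of handling) and by lowered mitotic genes. These list calls were all lost with an estimated correlation between genes (adjusted p from 0.194 to 0.371). The secretoglobin SCGB2A2 (mammaglobin A, a secreted breast epithelial protein; chromosome 11, 62270158 to 62273160) rose 44-fold, from 40.8 ± 0.75 to 1797 ± 403 CPM (SD, n = 3). The proliferation marker MKI67 fell 2.25-fold, from 190.5 ± 5.8 to 84.5 ± 1.4 CPM. ERBB2 itself (chromosome 17, 39688094 to 39728658), the amplified receptor gene of this line, stood at 11530 ± 277 CPM against 7653 ± 433. In all, 10968 genes were called, 5618 higher and 5350 lower, and 4637 of them changed at least 2-fold (2556 higher, 2081 lower).

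Of the 24 tested luminal and apocrine genes, 15 rose, 6 fell and 3 did not pass, the same as when adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 0.000997). That call was lost with an estimated correlation between genes (adjusted p = 0.371) and under limma-voom (adjusted p = 0.0543). SCGB1D2, a partner secretoglobin next to SCGB2A2 on chromosome 11, rose by a log2 fold change of 5.75 ± 0.20 (SE, adjusted p = 2.87e-12), and AZGP1, a secreted zinc-binding glycoprotein, rose 4.16-fold to 1331 ± 114 CPM. Other genes with high folds were the cytochrome CYP1A1, an aryl hydrocarbon receptor target (37.4-fold, to 78 ± 10.8 CPM), and TMEM238 (33.5-fold). TMEM238 kept a log2 fold change of 2.48 after the GC and length correction, from 5.06.

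Hypoxia-inducible genes were raised, with 20 of 25 up, 2 down and 3 not passing, and 20 up and 2 down adjusted over the list alone (median 0.69, camera adjusted p = 2.68e-05, and adjusted p = 0.371 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, rose from 10.2 ± 0.8 to 144.9 ± 27.9 CPM (log2 fold change 3.83 ± 0.16, adjusted p = 1.43e-11). CA9, a carbonic anhydrase induced by low oxygen, rose 11.6-fold, NDRG1 6.82-fold, ANKRD37 13.5-fold and VEGFA 1.54-fold. All but 2 of the 17 glycolysis genes rose and none fell, likewise over the list alone (median 0.98, camera adjusted p = 6.56e-06, and adjusted p = 0.371 with an estimated correlation). ALDOC rose 4.39-fold, PFKP 2.83-fold and GAPDH 2.38-fold. The glycolysis list has a median GC content of 53.3% against 48.8% for all genes, and its median fell to 0.46 after the GC and length correction, that of GAPDH also to 0.46 and that of PFKP to 0.90.

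Mitotic genes fell, 22 of 26 with 1 up and 3 not passing, the same over the list alone (median -1.02, camera adjusted p = 4.96e-08, and adjusted p = 0.194 with an estimated correlation). HMMR, a spindle-associated protein, fell from 45.6 ± 0.21 to 9.31 ± 0.31 CPM, the checkpoint kinase TTK fell 3.67-fold and the spindle motor KIF11 2.63-fold. These genes have a median GC content of 43.2%, and after the GC and length correction HMMR stood at -1.45 in place of -2.29 and KIF11 at -0.60 in place of -1.39. Heat shock genes fell too, 11 of 17 against 2 up and 4 not passing, the same over the list alone (median -0.64, camera adjusted p = 0.00549, and adjusted p = 0.459 with an estimated correlation). The chaperones HSPH1 (2.94-fold), DNAJB4 (4.4-fold) and HSP90AA1 (2.51-fold, from 3238 ± 82 to 1292 ± 115 CPM) were among them. The correction moved HSPH1 from -1.56 to -0.86 and DNAJB4 from -2.14 to -1.10.

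Immediate early genes, which respond to growth factor signalling, rose in 20 of 25 cases, with 2 down and 3 not passing, the same over the list alone (median 1.23, camera adjusted p = 3.49e-07, and adjusted p = 0.194 with an estimated correlation). EGR1 rose 4-fold, NR4A2 4.39-fold and the ETS factor ETV4 5.44-fold. The list has a median GC content of 55%, and after the GC and length correction its median was 0.39 and ETV4 moved from 2.44 to 1.57. Ribosomal protein genes rose in 43 of 46 cases with none down, likewise over the list alone (median 0.66, camera adjusted p = 4.96e-08, and adjusted p = 0.605 with an estimated correlation). RPL13 rose 2.83-fold, RPL27 2.38-fold and RPS19 2.14-fold. Their transcripts are short, with a median of 1823 bases against 3498 for all genes, and the correction brought the list's median to 0.44 and RPS19 to 0.51. The luminal median was 0.41 after it.

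Among receptor genes, EGFR (chromosome 7, 55019017 to 55211628) rose 2.07-fold to 176.8 ± 9.8 CPM and ERBB3 1.27-fold. The calls of ERBB2 (log2 fold change 0.59 ± 0.11, adjusted p = 0.000112) and of its amplicon neighbour GRB7 (0.60 ± 0.08) did not stand the GC and length correction: ERBB2 came to 0.07 (adjusted p = 0.39) and GRB7 turned to -0.22 (adjusted p = 0.00244), while ERBB3 came to 0.17. FASN, the fatty acid synthase, did not pass at 0.21 ± 0.11 (adjusted p = 0.0914), was called without monolayer replicate 3 (0.29, adjusted p = 0.0393) and turned to -0.88 (adjusted p = 3.13e-08) under it. The cell cycle inhibitor CDKN1A rose 1.71-fold but stood at 0.09 (adjusted p = 0.707) after the correction. HMGCS1 (-0.95) and KRT18 (-0.24) fell, to -0.33 and -0.80 with it, and FN1 rose 2.09-fold, TXNIP 1.58-fold. IFIT1, an interferon-induced gene, fell from 1.72 ± 1.2 to 0.197 ± 0.095 CPM, a log2 fold change of -3.13, or -2.39 without monolayer replicate 2.

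Several of the lowest fold changes fell on genes that, like TYRP1, were low in all small spheroid and capsule libraries. The matrix protein gene POSTN had 0 counts in small spheroids against 21.9 ± 9.7 CPM in monolayer, at least 301-fold lower. TYRP1 had 3 counts, a ratio of 336 to monolayer (95% interval 115 to 1630), and the cadherin gene CDH1 also 3, a ratio of 18.4 (6.09 to 90.9), and 2 of the 3 counts of each lay in small spheroid replicate 3. MLANA, another melanocyte gene, fell from 14.5 ± 9.5 to 0.102 ± 0.088 CPM, a log2 fold change of -7.14, or -6.44 without monolayer replicate 2 and -6.52 without small spheroid replicate 1. GJA1, TMSB4X and VIM had log2 fold changes of -5.28, -3.83 and -2.52, with monolayer 3 the lowest of the monolayer libraries for each. SAMD9, an interferon-inducible gene, fell 13.5-fold. The small nuclear RNA gene RN7SK stood at 52.3 CPM in small spheroid replicate 3 against 5.13 and 5.00 in the other replicates, so its log2 fold change of 5.30 came to 3.25 without that library.

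Fold changes in this comparison followed GC content across genes (Spearman rho 0.668). With library totals in place of TMM the median log2 fold change of all genes shifted to -0.145, and 43.6% of called genes were higher against 51.2%.

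Large spheroids differed from monolayer by raised hypoxia genes and lowered mitotic genes, list calls kept with an estimated correlation (adjusted p = 0.00667 and adjusted p = 0.00036). EGLN3 rose 21.9-fold to 222.8 ± 14.7 CPM, and ERO1A, an oxidoreductase of the endoplasmic reticulum induced by low oxygen, rose 6.31-fold to 542.9 ± 21 CPM (log2 fold change 2.66 ± 0.07, adjusted p = 2.48e-13). MKI67 fell 5.98-fold to 31.8 ± 3.2 CPM. EGFR rose 3.6-fold to 307.8 ± 7.2 CPM, whereas ERBB2 was lower, at 6065 ± 473 CPM. The comparison called 8669 genes, 4354 higher and 4315 lower, 2674 of them at least 2-fold (1466 higher, 1208 lower).

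The hypoxia list held 23 risers, no faller and 2 genes not passing, the same over the list alone (median 1.36, camera adjusted p = 3.66e-31), and the call held with an estimated correlation (adjusted p = 0.00667). P4HA1, a collagen prolyl hydroxylase, rose 6.42-fold to 1311 ± 42 CPM, CA9 9.42-fold, VEGFA 2.16-fold and ANKRD37 24.8-fold. Glycolysis rose in 15 of 17 genes, with none down and the same count over the list alone (median 0.83, camera adjusted p = 7.03e-09, and adjusted p = 0.132 with an estimated correlation). ALDOC rose 5.6-fold, PFKP 2.75-fold and GAPDH 2.09-fold.

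All 26 mitotic genes fell, also over the list alone (median -2.14, camera adjusted p = 4.05e-56, and adjusted p = 0.00036 with an estimated correlation). HMMR fell 9.38-fold, the mitotic kinesin KIF20A 5.86-fold and the spindle factor TPX2 4.26-fold, and KIF14, a kinesin of cytokinesis, fell 10.8-fold. DNA replication genes fell in 22 of 27 cases, with 2 up and 3 not passing, the same over the list alone (median -0.69, camera adjusted p = 1.36e-06, and adjusted p = 0.0681 with an estimated correlation). RRM2, the small subunit of ribonucleotide reductase, fell 3.37-fold and CDC45 3.33-fold.

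Lipid synthesis genes were lower. Of the 22 cholesterol synthesis genes 15 fell, 1 rose and 6 did not pass, the same over the list alone (median -0.44, camera adjusted p = 0.000474, and adjusted p = 0.443 with an estimated correlation), with FDPS down 2.57-fold. Of the 18 fatty acid genes 10 fell, 3 rose and 5 did not pass, and 11 fell and 3 rose adjusted over the list alone (median -0.54, camera adjusted p = 0.0264, and adjusted p = 0.132 with an estimated correlation). The desaturase SCD fell 1.98-fold to 808.4 ± 44.2 CPM, ELOVL5 2-fold, LPIN1 1.63-fold and FASN 1.88-fold. Heat shock genes fell in 13 of 17 cases with none up, the same over the list alone (median -0.64, camera adjusted p = 0.000187, and adjusted p = 0.183 with an estimated correlation), among them HSPH1 (2.57-fold), DNAJB4 (3.02-fold) and HSP90AB1 (1.58-fold).

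The integrated stress response list, targets of ATF4 under amino acid shortage and related stress, had 13 genes up, 3 down and 8 not passing, and 14 up and 3 down over the list alone (median 0.40, camera adjusted p = 0.00178, and adjusted p = 0.32 with an estimated correlation). VLDLR rose 8.38-fold, ATF3 5.42-fold and TRIB3 2.57-fold, and the list's median was 0.26 after the GC and length correction. Immediate early genes rose in 19 of 25 cases with none down, the same over the list alone (median 0.99, camera adjusted p = 3.7e-11, and adjusted p = 0.0273 with an estimated correlation). FOS rose 15.7-fold, ETV4 8.56-fold and EGR1 3.71-fold. Ribosomal protein genes rose in 42 of 46 cases with 1 down and 3 not passing, the same over the list alone (median 0.51, camera adjusted p = 6.69e-08, and adjusted p = 0.443 with an estimated correlation), RPS27 by 3.3-fold, RPL13 by 1.91-fold and RPL10 by 1.88-fold.

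Luminal genes rose in 12 of 24 cases with 8 down and 4 not passing, the same over the list alone (median 0.19, camera adjusted p = 0.00652, and adjusted p = 0.32 with an estimated correlation). SCGB2A2 rose 24.7-fold to 1010 ± 150 CPM, SCGB1D2 31.8-fold and ELF3, an epithelial ETS factor, 2.5-fold. Of 19 genes of PI3K-AKT and FOXO feedback 9 rose, 3 fell and 7 did not pass, the same over the list alone (median 0.28, camera adjusted p = 0.0383, and adjusted p = 0.183 with an estimated correlation). CITED2 rose 2.81-fold, BCL6 2.46-fold and PIK3IP1, an inhibitor of PI3K, 3.25-fold. This list's call ended without monolayer replicate 2 (adjusted p = 0.0576) or large spheroid replicate 3 (adjusted p = 0.0531). Under limma-voom the luminal and PI3K lists gave adjusted p = 0.238 and 0.0818.

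Of single genes, the metal-binding MT1X rose 48.6-fold to 14.4 ± 0.64 CPM, PPFIA4 37.9-fold and the lipase CEL 29.7-fold. DIO2, a deiodinase of thyroid hormone, fell 14.8-fold, OGDHL 9.98-fold, LRTM2 9.61-fold and the synaptic vesicle gene SYP 8.84-fold. ERBB3 rose 1.21-fold and FN1 1.61-fold. VIM fell 2.33-fold. GRB7 (0.06 ± 0.08), CDKN1A (-0.37 ± 0.19), CDH1 (-0.37 ± 0.43), IFIT1 (-0.61 ± 0.42) and TXNIP (-0.13 ± 0.16) did not pass. CDKN1A was called under the GC and length correction (-0.52, adjusted p = 0.0381) and IFIT1 without monolayer replicate 3 (-0.99, adjusted p = 0.0297).

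The calls of ERBB2 (-0.34 ± 0.11, adjusted p = 0.0144), HMGCS1 (-0.38) and KRT18 (-0.19) ended with 1 library left out. ERBB2 gave adjusted p = 0.0614 without monolayer replicate 3 and 0.0633 without large spheroid replicate 3. HMGCS1 gave 0.0549 to 0.0948 (-0.34 to -0.39) without monolayer 2 or 3 or large spheroid 1, 2 or 3. KRT18 gave 0.0517 to 0.0974 (-0.17 to -0.20) without monolayer 2 or 3 or large spheroid 1 or 2. Spearman rho with GC content was 0.189.

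Capsule cultures differed from monolayer by raised replication, nuclear respiratory chain and luminal genes and lowered mitochondrially encoded genes, with no call for mitosis. These list calls were lost with an estimated correlation (adjusted p from 0.088 to 0.533). MKI67 stood at 179.3 ± 30.7 CPM against 190.5 ± 5.8 (log2 fold change -0.09 ± 0.10, adjusted p = 0.467). The replication factor UHRF1 rose 4.31-fold, to 23.9 ± 2.2 CPM. SCGB2A2 rose 27.5-fold to 1124 ± 46 CPM, and ERBB2 stood at 9873 ± 1854 CPM. Calls numbered 10013, 5230 higher and 4783 lower, with 3411 at least 2-fold (2047 higher, 1364 lower).

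DNA replication genes rose in 25 of 27 cases with none down, the same over the list alone (median 0.94, camera adjusted p = 9.33e-08, and adjusted p = 0.088 with an estimated correlation). MCM3 and MCM7, parts of the replicative helicase, rose 2.59-fold and 2.14-fold. The mitosis list did not pass, with 12 up, 1 down and 13 not passing (median 0.11, camera adjusted p = 0.276), although after the GC and length correction it was called at a median of 0.29 (adjusted p = 0.00766) and MKI67 turned to 0.23 (adjusted p = 0.0189).

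Nuclear genes of oxidative phosphorylation rose in 24 of 35 cases, with 2 down and 9 not passing, the same over the list alone (median 0.58, camera adjusted p = 3.79e-06, and adjusted p = 0.533 with an estimated correlation). NDUFA1 and NDUFA2, subunits of complex I, rose 2.97-fold and 3.02-fold, and ATP5MC1 of the ATP synthase 2.57-fold. The 13 mitochondrially encoded genes went the other way, 10 down, 1 up and 2 not passing, and 10 down and 2 up over the list alone (median -0.52, camera adjusted p = 0.000233, and adjusted p = 0.533 with an estimated correlation). ND4L fell 4.66-fold, ND1 3.07-fold and ND2 2.97-fold, from 4111 ± 148 to 1385 ± 45 CPM. Protein-coding mitochondrial transcripts took 2.554 to 2.741% of counts in the capsule libraries and 4.245 to 5.356% in the other 9 libraries. Ribosomal protein genes rose in 37 of 46 cases, with 1 down and 8 not passing, and 38 up and 1 down over the list alone (median 0.66, camera adjusted p = 3.28e-07, and adjusted p = 0.533 with an estimated correlation). RPL27 rose 2.6-fold, RPL35 2.66-fold and RPS19 2.09-fold. With the GC and length correction the medians of these 3 lists were 0.35, -0.97 and 0.33, RPL35 came from 1.41 to 0.33, NDUFA1 from 1.57 to 0.90 and NDUFA2 from 1.60 to 0.97.

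Hypoxia genes rose in 12 of 25 cases, with 2 down and 11 not passing, the same over the list alone (median 0.39, camera adjusted p = 0.0284, and adjusted p = 0.533 with an estimated correlation). EGLN3 rose 5.69-fold, NDRG1 2.72-fold, ANKRD37 7.84-fold and CA9 4.28-fold, but VEGFA fell 1.37-fold to 122.4 ± 14.4 CPM. Glycolysis rose in 12 of 17 cases with 3 down and 2 not passing, the same over the list alone (median 0.77, camera adjusted p = 0.0106, and adjusted p = 0.533 with an estimated correlation). ENO1 rose 2.12-fold, PKM 1.89-fold and GAPDH 1.8-fold. This call ended under the GC and length correction, at a median of 0.27 (adjusted p = 0.126), where GAPDH moved from 0.85 to 0.33. Immediate early genes rose in 16 of 25 cases, with 3 down and 6 not passing, the same over the list alone (median 0.84, camera adjusted p = 0.000321, and adjusted p = 0.424 with an estimated correlation). ETV4 rose 4.37-fold, SPRY4, a feedback inhibitor of receptor signalling, 2.65-fold and KLF2 19.1-fold.

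The integrated stress response list had 15 down, 4 up and 5 not passing, the same over the list alone (median -0.39, camera adjusted p = 0.0106, and adjusted p = 0.533 with an estimated correlation), and -0.60 after the GC and length correction. Asparagine synthetase ASNS fell 2.94-fold, PSAT1 of serine synthesis 2.37-fold and the cystine transporter SLC7A11 5.48-fold. Interferon response genes fell in 18 of 25 cases, with 5 up and 2 not passing, the same over the list alone (median -0.83, camera adjusted p = 0.009, and adjusted p = 0.424 with an estimated correlation). BST2 fell 3.62-fold, SAMD9 5.94-fold and the RNA sensor IFIH1 2.47-fold. The interferon call ended without capsule replicate 1 (adjusted p = 0.0582). Targets of YAP-TEAD and SRF fell in 17 of 27 cases, with 3 up and 7 not passing, and 18 down and 4 up over the list alone (median -0.66, camera adjusted p = 0.000233, and adjusted p = 0.451 with an estimated correlation). TGFB2 fell 10.3-fold, TEAD1 2.61-fold and vinculin VCL 2.03-fold. Its member ANKRD1, chosen after its values were seen, stood at 10.7, 8.49 and 3.03 CPM of the library total in monolayer and at 0.127, 0.208 and 0.141 in capsules, a pattern like that of POSTN and TYRP1. Fibroblast markers had a median of -1.23 here (camera adjusted p = 0.232).

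Luminal genes rose in 13 of 24 cases, with 6 down and 5 not passing, the same over the list alone (median 0.36, camera adjusted p = 0.00861, and adjusted p = 0.451 with an estimated correlation). SCGB1D2 rose 29.1-fold and AGR2, a disulphide isomerase of secretory epithelium, 6.03-fold. The list's median was 0.06 after the GC and length correction, and its adjusted p was 0.125 under limma-voom.

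MT1X rose 54.4-fold. Small RNA genes headed the risers but differed between replicates: RN7SK stood at 51.3, 51.1 and 121.4 CPM in capsule 1, 2 and 3, RMRP at 9.42, 11.6 and 31.8, RPPH1 at 12.3, 10.9 and 49.8, and the 2 copies of MIR3648 at 2.85, 7.57 and 45.9 and at 1.14, 4.61 and 29.9. Without capsule replicate 3 the log2 fold change of RMRP came from 7.47 to 6.73, that of RPPH1 from 5.29 to 4.22 and that of the first MIR3648 copy from 8.10 to 6.26. Without monolayer replicate 1 that of RMRP was 8.48. The second MIR3648 copy, with 2 counts in monolayer, had a ratio of 377 (95% interval 104 to 3120). Its log2 fold change of 8.29 came to 6.24 without capsule replicate 3, 7.67 without monolayer replicate 2 and 10.66 without monolayer replicate 1.

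Several of the lowest genes were those low in small spheroids too. POSTN had 1 count in capsules, a ratio of 983 (95% interval 176 to 38800), TYRP1 had 2, a ratio of 543 (150 to 4490), and CDH1 had 2, a ratio of 29.8 (8 to 250). GJA1 fell 82.3-fold, the melanosome gene PMEL 18-fold, GSTP1 14.8-fold and VIM 10.1-fold. MLANA had a log2 fold change of -5.24, or -4.55 without monolayer replicate 2. All counts of POSTN, TYRP1 and CDH1 in capsules lay in replicate 1.

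Of the remaining fixed genes, ERBB2 rose (0.37 ± 0.11, adjusted p = 0.00691), to 0.17 after the GC and length correction. FASN rose (0.38 ± 0.11) and turned to -0.11 (adjusted p = 0.232) with it, CDKN1A rose 1.68-fold and came to 0.36 (adjusted p = 0.117), and GRB7, at 0.05 ± 0.08 without a call, turned to -0.44 (adjusted p = 1.38e-06). Without capsule replicate 1 CDKN1A stood at 0.44 in place of 0.75. EGFR (88 ± 15.1 against 85.5 ± 2.8 CPM), ERBB3 (-0.09 ± 0.08), HMGCS1 (0.26 ± 0.14) and TXNIP (-0.15 ± 0.16) did not pass. EGFR was called under the GC and length correction (0.34, adjusted p = 0.00171) and without capsule replicate 1 (0.18, adjusted p = 0.0181). HMGCS1 was called under the correction (0.48, adjusted p = 8.32e-05) and without capsule replicate 2 or 3 (0.37 and 0.39, adjusted p = 0.0314 and 0.0203). KRT18 fell 1.16-fold. IFIT1 fell, at -1.89, or -1.15 without monolayer replicate 2. FN1 rose 1.29-fold, a call that ended with library totals (adjusted p = 0.0556) and without monolayer replicate 3, capsule replicate 2 or capsule replicate 3 (adjusted p = 0.148, 0.138 and 0.0641). Spearman rho with GC content was 0.43.

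By their labels large and small spheroids are the same kind of culture, liquid overlay spheroids, at different size. Their titles also differ in the letters UP, so differences between them cannot be credited to size alone. Large spheroids had higher hypoxia genes and EGFR and lower mitotic genes and ERBB2, though the hypoxia call was lost with an estimated correlation (adjusted p = 0.268). ERO1A stood 3.36-fold higher (542.9 ± 21 against 161.4 ± 4.1 CPM) and KDM3A, a histone demethylase induced by low oxygen, 2.63-fold. MKI67 was 2.66-fold lower and ERBB2 1.9-fold lower. Calls numbered 10064, 4992 higher and 5072 lower in large spheroids, 3005 of them at least 2-fold (1286 higher, 1719 lower).

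Hypoxia genes were higher in 17 of 25 cases, lower in 1 and not passing in 7, the same over the list alone (median 0.78, camera adjusted p = 8.59e-08, and adjusted p = 0.268 with an estimated correlation). VEGFA was 1.41-fold higher, while CA9 did not pass (-0.30 ± 0.19, adjusted p = 0.177). All 26 mitotic genes were lower, also over the list alone (median -1.14, camera adjusted p = 5.45e-15), a call kept with an estimated correlation (adjusted p = 0.0373). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, was 3.3-fold lower and KIF20A 3.15-fold. Replication genes were lower in 16 of 27 cases, higher in 3 and not passing in 8, the same over the list alone (median -0.53, camera adjusted p = 0.00302, and adjusted p = 0.419 with an estimated correlation), with CDC45 down 3.27-fold and MCM7 1.94-fold.

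Cholesterol synthesis genes were lower in 14 of 22 cases, higher in 3 and not passing in 5, the same over the list alone (median -0.46, camera adjusted p = 0.00302, and adjusted p = 0.991 with an estimated correlation). DHCR7, which makes cholesterol from its last precursor, was 2.12-fold lower. HMGCS1 went the other way, at 0.57 ± 0.15, and stood at 0.04 (adjusted p = 0.717) after the GC and length correction. Nuclear oxidative phosphorylation genes were lower in 20 of 35 cases, higher in 2 and not passing in 13, the same over the list alone (median -0.37, camera adjusted p = 0.00373, and adjusted p = 0.991 with an estimated correlation). ATP5MC1 was 1.9-fold lower, and CYC1, at -0.98 ± 0.08, came to -0.02 (adjusted p = 0.863) under the correction. Mitochondrially encoded genes were lower in 9 of 13 cases, higher in 2 and not passing in 2, the same over the list alone (median -0.53, camera adjusted p = 0.00373, and adjusted p = 0.991 with an estimated correlation). ATP8 was 3.85-fold lower and ND1 2.19-fold. Mitochondrial ribosomal RNA, in contrast, took 2.489 to 2.724% of counts in large spheroids and 0.6885 to 1.132% in the other 9 libraries.

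RBP4, a retinol carrier, was 25.4-fold lower in large spheroids, the aldo-keto reductase AKR1C1 18.4-fold and the signalling ligand WNT6 11.8-fold. SLC2A3, a glucose transporter, was 8.27-fold higher and PKIA 7.16-fold. POSTN was at least 228-fold higher, GJA1 26.6-fold, TMSB4X 10.4-fold and VIM 2.46-fold, genes also higher in monolayer than in small spheroids. CDH1 had a ratio of 13.9 (95% interval 4.5 to 69.3) on 3 counts in small spheroids. SNORD3A and RPPH1 stood at 48.4 and 51.4 CPM in small spheroid replicate 3 and no higher than 5.13 in its partners. Without that library their log2 fold changes of -3.85 and -3.81 came to -1.73 (adjusted p = 0.13) and -1.54 (adjusted p = 0.0574), and under limma-voom the adjusted p was 0.0784 and 0.0612.

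EGFR was 1.74-fold higher and IFIT1 5.74-fold. FASN was 2.17-fold lower, CDKN1A 2.21-fold, TXNIP 1.72-fold and GRB7 1.46-fold. ERBB3 (-0.07 ± 0.08) and KRT18 (0.05 ± 0.07) did not pass, but KRT18 was called under the GC and length correction (0.47, adjusted p = 3.12e-06) and with library totals (0.16, adjusted p = 0.0401). FN1 was 1.3-fold lower, a call lost with library totals (adjusted p = 0.0925), without small spheroid replicate 2 (0.135) and without large spheroid replicate 1 (0.0748). Fold changes followed GC content with a Spearman rho of -0.657, and the correction moved ERBB2 from -0.93 to -0.48, FASN from -1.12 to -0.23, CDKN1A from -1.14 to -0.61, FN1 from -0.38 to -0.85 and GRB7 from -0.55 to 0.09 (adjusted p = 0.179). It also moved ERO1A from 1.75 to 1.14, DHCR7 from -1.08 to -0.56, MCM7 from -0.95 to -0.49 and WNT6 from -3.56 to -2.20. Glycolysis, with 5 genes higher, 6 lower and 6 not passing (median -0.16, camera adjusted p = 0.987), turned to a median of 0.19 (adjusted p = 0.0207) with it. With library totals the median log2 fold change of all genes was 0.107, and 56.7% of called genes were higher against 49.6%.

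Capsules against small spheroids gave the fewest calls, 7892 (4095 higher in capsules, 3797 lower), 1498 of them at least 2-fold (742 higher, 756 lower). Capsules had higher mitotic and replication genes and lower stress response and mitochondrially encoded genes, the last 2 list calls being lost with an estimated correlation (adjusted p = 0.0969 for both). HMMR stood 3.6-fold higher (33.6 ± 2.5 against 9.31 ± 0.31 CPM), RRM2 3.01-fold higher and MKI67 2.12-fold. CHAC1, an ATF4 target that degrades glutathione, was 6.39-fold lower. With library totals in place of TMM, 62.9% of called genes were higher in capsules against 51.9%, and the median of all genes was 0.116.

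Mitotic genes were higher in 25 of 26 cases with none lower, and in 26 over the list alone (median 1.24, camera adjusted p = 3.12e-31, and adjusted p = 0.00256 with an estimated correlation), BUB1B of the spindle checkpoint by 2.73-fold. Replication genes were higher in 24 of 27 cases with none lower, the same over the list alone (median 1.08, camera adjusted p = 6.41e-23, and adjusted p = 0.00256 with an estimated correlation), RRM1 by 2.27-fold. Replication-dependent histones were higher in 9 of 17 cases, lower in 1 and not passing in 7, and higher in 11 and lower in 1 over the list alone (median 0.56, camera adjusted p = 0.0364, and adjusted p = 0.37 with an estimated correlation). H1-2 was 2.15-fold and H1-4 4.82-fold higher. The histone call ended with library totals (adjusted p = 0.078), the GC and length correction (0.0862) and without small spheroid replicate 1 (0.0549) or capsule replicate 1 (0.105).

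The integrated stress response list was lower in 17 of 24 genes, higher in 1 and not passing in 6, the same over the list alone (median -0.78, camera adjusted p = 1.51e-09, and adjusted p = 0.0969 with an estimated correlation), with VLDLR down 3.76-fold. Mitochondrially encoded genes were lower in 11 of 13 cases with none higher, the same over the list alone (median -0.97, camera adjusted p = 3.61e-17, and adjusted p = 0.0969 with an estimated correlation), ND1 by 4.1-fold and ND2 by 2.45-fold. Their nuclear partners were higher in 23 of 35 cases, lower in 5 and not passing in 7, the same over the list alone (median 0.41, camera adjusted p = 0.000575, and adjusted p = 0.433 with an estimated correlation), with ATP5MC1 1.58-fold and NDUFB3 1.84-fold higher. Heat shock genes were higher in 11 of 17 cases, lower in 2 and not passing in 4, and higher in 11 and lower in 3 over the list alone (median 0.59, camera adjusted p = 0.000221, and adjusted p = 0.226 with an estimated correlation). HSP90AA1 stood at 3335 ± 537 against 1292 ± 115 CPM, and CHORDC1 was 2.6-fold higher. After the GC and length correction the medians of the nuclear respiratory and heat shock lists were 0.26 and 0.38, NDUFB3 came from 0.88 to 0.45 and CHORDC1 from 1.38 to 0.89.

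Hypoxia genes were lower in 16 of 25 cases, higher in 3 and not passing in 6, the same over the list alone (median -0.35, camera adjusted p = 0.000192, and adjusted p = 0.282 with an estimated correlation), NDRG1 by 2.5-fold, VEGFA by 2.1-fold and CA9 by 2.7-fold. Glycolysis was lower in 11 of 17 cases, higher in 1 and not passing in 5, the same over the list alone (median -0.40, camera adjusted p = 0.000221, and adjusted p = 0.288 with an estimated correlation), ALDOC by 2.45-fold and the lactate transporter SLC16A3 by 1.85-fold. The correction brought the glycolysis median to -0.14 and SLC16A3 from -0.89 to -0.41. Immediate early genes were lower in 12 of 25 cases, higher in 2 and not passing in 11, and lower in 14 and higher in 2 over the list alone (median -0.40, camera adjusted p = 0.00143, and adjusted p = 0.245 with an estimated correlation). EGR1 was 2.24-fold and JUND 2.64-fold lower. This call ended under the correction, at -0.07 (adjusted p = 0.0593), where JUND moved from -1.40 to -0.85.

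PI3K-AKT and FOXO feedback genes were lower in 11 of 19 cases, higher in 2 and not passing in 6, the same over the list alone (median -0.35, camera adjusted p = 0.000981, and adjusted p = 0.0901 with an estimated correlation), FBXO32 by 2.85-fold and BCL6 by 2.45-fold. Cholesterol synthesis was higher in 12 of 22 cases, lower in 2 and not passing in 8, and higher in 13 and lower in 2 over the list alone (median 0.38, camera adjusted p = 0.0152, and adjusted p = 0.438 with an estimated correlation), SQLE by 1.62-fold and HMGCS1 by 2.31-fold. Without capsule replicate 1 that median was 0.20. YAP-TEAD and SRF targets were lower in 12 of 27 cases, higher in 4 and not passing in 11, the same over the list alone (median -0.23, camera adjusted p = 0.0206, and adjusted p = 0.37 with an estimated correlation), with ACTG1 2.16-fold and TGFB2 3.33-fold lower. Mesenchymal genes were lower in 9 of 23 cases, higher in 1 and not passing in 13, the same over the list alone (median -0.61, camera adjusted p = 0.0226, and adjusted p = 0.433 with an estimated correlation). LOXL2, a collagen cross-linking enzyme, was 7.15-fold lower. The mesenchymal median was -0.35 after the correction, and its call ended without capsule replicate 2 (adjusted p = 0.0508).

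ABCG2, a drug efflux pump, was 7.09-fold higher in capsules, the calcium-binding S100A8 6.48-fold and CLCA2 6.13-fold. SCARNA2 was higher by 2.57 on the log2 scale and by 3.46 without small spheroid replicate 3. CASP14, an epidermal caspase, was 7.91-fold lower, CBS 6.35-fold and CNNM1 5.92-fold. EGFR was 2.01-fold lower, TXNIP 1.75-fold, FN1 1.62-fold, GRB7 1.47-fold and ERBB3 1.35-fold. The correction moved GRB7 from -0.55 to -0.23 and ERBB3 from -0.43 to -0.25. ERBB2 (-0.22 ± 0.11, adjusted p = 0.0943), FASN (0.17 ± 0.11), CDKN1A (-0.03 ± 0.19), IFIT1 (1.24 ± 0.76) and KRT18 (0.02 ± 0.07) did not pass. FASN was called under the correction (0.77, adjusted p = 4.52e-07), with library totals (0.27, adjusted p = 0.0471) and without capsule replicate 1 (0.30, adjusted p = 0.00272). KRT18 was called under the correction (0.21, adjusted p = 0.00747) and ERBB2 without capsule replicate 2 (-0.32, adjusted p = 0.0263). CDH1 had 2 and 3 counts, too few to detect a difference at this depth. VIM was 1.77-fold lower, a call lost with library totals (adjusted p = 0.0698), under limma-voom (0.0874) and without small spheroid replicate 2 or 3 or capsule replicate 2 or 3 (adjusted p = 0.0686, 0.171, 0.149 and 0.0509). Spearman rho with GC content was -0.5.

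Capsules against large spheroids showed the widest gap between formats in the medians of the mitosis and replication lists. MKI67 was 5.63-fold higher in capsules, KIF20A 6.72-fold, UBE2C 6.57-fold and CDC45 6.92-fold (35.6 ± 1.5 against 5.13 ± 0.35 CPM). Hypoxia and stress response genes were lower, ERO1A by 4.17-fold and VLDLR by 9.44-fold, though the stress response call was lost with an estimated correlation (adjusted p = 0.0854). EGFR was 3.5-fold lower and ERBB2 1.63-fold higher. Calls numbered 9511, 4873 higher in capsules and 4638 lower, 3205 of them at least 2-fold (1788 higher, 1417 lower), or 3204 with genes at 0 in a format set to their bound.

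All 26 mitotic genes were higher, also over the list alone (median 2.40, camera adjusted p = 7.66e-56, and adjusted p = 0.000205 with an estimated correlation). Replication genes were higher in 24 of 27 cases with none lower, and in 25 over the list alone (median 1.70, camera adjusted p = 7.17e-25, and adjusted p = 0.00106 with an estimated correlation), RRM2 by 5.02-fold. Cholesterol synthesis was higher in 18 of 22 cases with none lower, the same over the list alone (median 0.93, camera adjusted p = 3.09e-07, and adjusted p = 0.299 with an estimated correlation), MVK by 2.85-fold. Fatty acid genes were higher in 11 of 18 cases, lower in 1 and not passing in 6, the same over the list alone (median 0.41, camera adjusted p = 0.00493, and adjusted p = 0.0549 with an estimated correlation). ELOVL6 was 3.02-fold, THRSP 3.74-fold and FASN 2.44-fold higher.

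Hypoxia genes were lower in 22 of 25 cases, higher in 1 and not passing in 2, the same over the list alone (median -1.29, camera adjusted p = 2.16e-16, and adjusted p = 0.0372 with an estimated correlation). MXI1 was 4.13-fold, VEGFA 2.95-fold and CA9 2.2-fold lower. Glycolysis was lower in 9 of 17 cases, higher in 2 and not passing in 6, the same over the list alone (median -0.25, camera adjusted p = 0.02, and adjusted p = 0.62 with an estimated correlation), with ALDOC 3.12-fold and hexokinase HK2 2.41-fold lower. The integrated stress response was lower in 20 of 24 cases, higher in 2 and not passing in 2, the same over the list alone (median -0.90, camera adjusted p = 3.6e-09, and adjusted p = 0.0854 with an estimated correlation), with ASNS at 57.1 ± 9.5 against 259.5 ± 1.4 CPM. PI3K-AKT and FOXO feedback genes were lower in 12 of 19 cases, higher in 2 and not passing in 5, the same over the list alone (median -0.66, camera adjusted p = 0.000185, and adjusted p = 0.0398 with an estimated correlation), FBXO32 by 3.33-fold and FOXO3 by 2.82-fold.

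Oxidative phosphorylation genes of the nucleus were higher in 30 of 35 cases with none lower, the same over the list alone (median 0.55, camera adjusted p = 1.7e-08, and adjusted p = 0.367 with an estimated correlation), ATP5MC1 by 2.99-fold and NDUFB8 by 2.7-fold. Mitochondrially encoded genes were lower in 9 of 13 cases, higher in 2 and not passing in 2, the same over the list alone (median -0.40, camera adjusted p = 0.0118, and adjusted p = 0.62 with an estimated correlation), and -0.75 after the GC and length correction. ND4L was 3.64-fold and ND4 2.01-fold lower. YAP-TEAD and SRF targets were lower in 17 of 27 cases, higher in 7 and not passing in 3, the same over the list alone (median -0.46, camera adjusted p = 0.00125, and adjusted p = 0.327 with an estimated correlation), TGFB2 by 14.3-fold and MYOF by 2.65-fold. Without capsule replicate 1 the median of this list was -0.30. Fibroblast markers had a median of -0.88 (camera adjusted p = 0.566). Heat shock genes were higher in 11 of 17 cases with none lower, the same over the list alone (median 0.53, camera adjusted p = 0.014, and adjusted p = 0.424 with an estimated correlation), STIP1 by 1.76-fold and HSP90AA1 by 2.03-fold.

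CCK, a peptide hormone, was 36.9-fold higher in capsules, and the mitochondrial transfer RNA gene TRNN 10.8-fold lower. RMRP, RN7SK and the MIR3648 copies were higher with the replicate spread given above. Without capsule replicate 3 the log2 fold change of RMRP went from 5.86 to 5.12 and those of the MIR3648 copies from 5.57 to 3.72 and from 5.70 to 3.66. Without large spheroid replicate 1 they were 6.94, 8.25 and 6.38. The GC and length correction gave 3.68 and 3.79 for the copies. SLC2A3 was 12.7-fold lower. POSTN, with 1 count in capsules, had a ratio of 749 (95% interval 134 to 29600) and CDH1, with 2, of 22.4 (5.92 to 190). GJA1 was 56.3-fold and VIM 4.35-fold lower.

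CDKN1A was 2.17-fold higher and ERBB3 1.29-fold lower. HMGCS1 was higher at 0.63 ± 0.14, and at 0.35 without capsule replicate 1. IFIT1 was lower at -1.28 ± 0.53 (adjusted p = 0.0452), a call lost under the GC and length correction (0.0623), limma-voom (0.0745), and without large spheroid replicate 2 or 3 or capsule replicate 2 or 3 (adjusted p = 0.121, 0.0761, 0.145 and 0.0817). FN1 (-0.32 ± 0.14, adjusted p = 0.0546), GRB7 (-0.01 ± 0.08), KRT18 (-0.03 ± 0.07) and TXNIP (-0.02 ± 0.16) did not pass. FN1 was called with library totals (adjusted p = 0.0473), DESeq2 (0.0494), limma-voom (0.0486), the replicate block (0.0365), without mitochondrially encoded and ribosomal protein genes (0.0463) and without large spheroid replicate 1 (0.0487) or capsule replicate 2 (0.0175). The correction called GRB7 (-0.32, adjusted p = 6.47e-05) and KRT18 (-0.26, adjusted p = 0.000955). Spearman rho with GC content was 0.288.

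**Figure D2:**
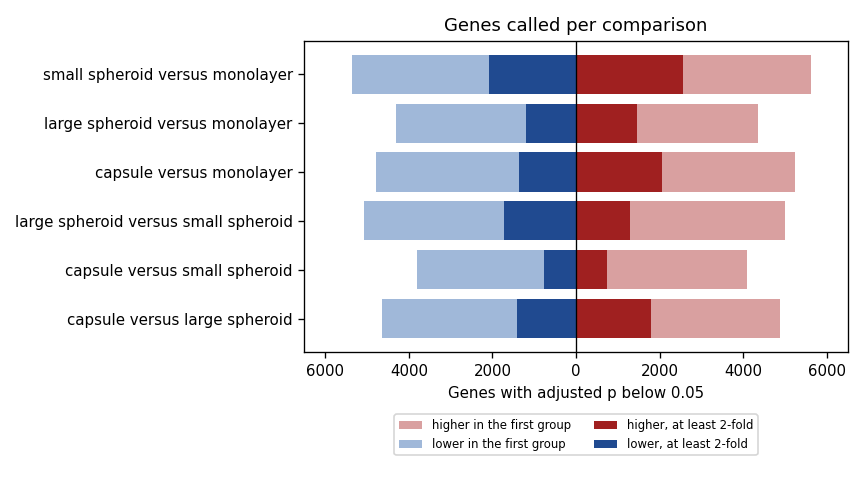
Number of genes called at adjusted p below 0.05 in each of the 6 comparisons, drawn to the right where the first format was higher and to the left where it was lower, with genes changed at least 2-fold in the darker shade. Calls ranged from 7892 for capsule against small spheroid to 10968 for small spheroid against monolayer.

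The 3 formats other than monolayer shared many calls against it. In total 4414 genes were called in the same direction in all 3 (2319 higher, 2095 lower), where independent lists would share 1035 and unchanged groups simulated against the same controls shared 0.05 on average and 1 at most. SCGB2A2, SCGB1D2, EGLN3, ANKRD37, ETV4 and CA9 were higher in all 3, and VIM and KRT18 lower. At least 2-fold, 622 genes were higher and 264 lower in all 3. Opposite calls in at least 2 formats numbered 1837, among them ERBB2, VEGFA and FASN. Small spheroid and capsule shared 3982 higher and 3713 lower genes with 497 in opposite directions (independent lists 1936, 1686 and 3615). Small and large spheroid shared 2979 and 2837 with 988 opposite (1612, 1521 and 3132), and large spheroid and capsule 2583 and 2395 with 1282 opposite (1501, 1360 and 2859). Fold changes against monolayer correlated across genes at 0.811 for small spheroid and capsule (covariance 0.97), 0.587 for small and large spheroid (0.601) and 0.463 for large spheroid and capsule (0.435). Simulated unchanged groups gave correlations of 0.466, 0.476 and 0.476 and a covariance of 0.0215 for each pair. With 3 monolayer libraries the controls could not be split, so part of the excess may come from sharing them. Small spheroid and capsule titles also both lack the letters UP, which monolayer titles carry. Fold changes of both formats against monolayer followed GC content (Spearman rho 0.668 and 0.43). What these 2 formats share can therefore not be told apart from a preparation, run or GC content effect here.

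**Figure D3:**
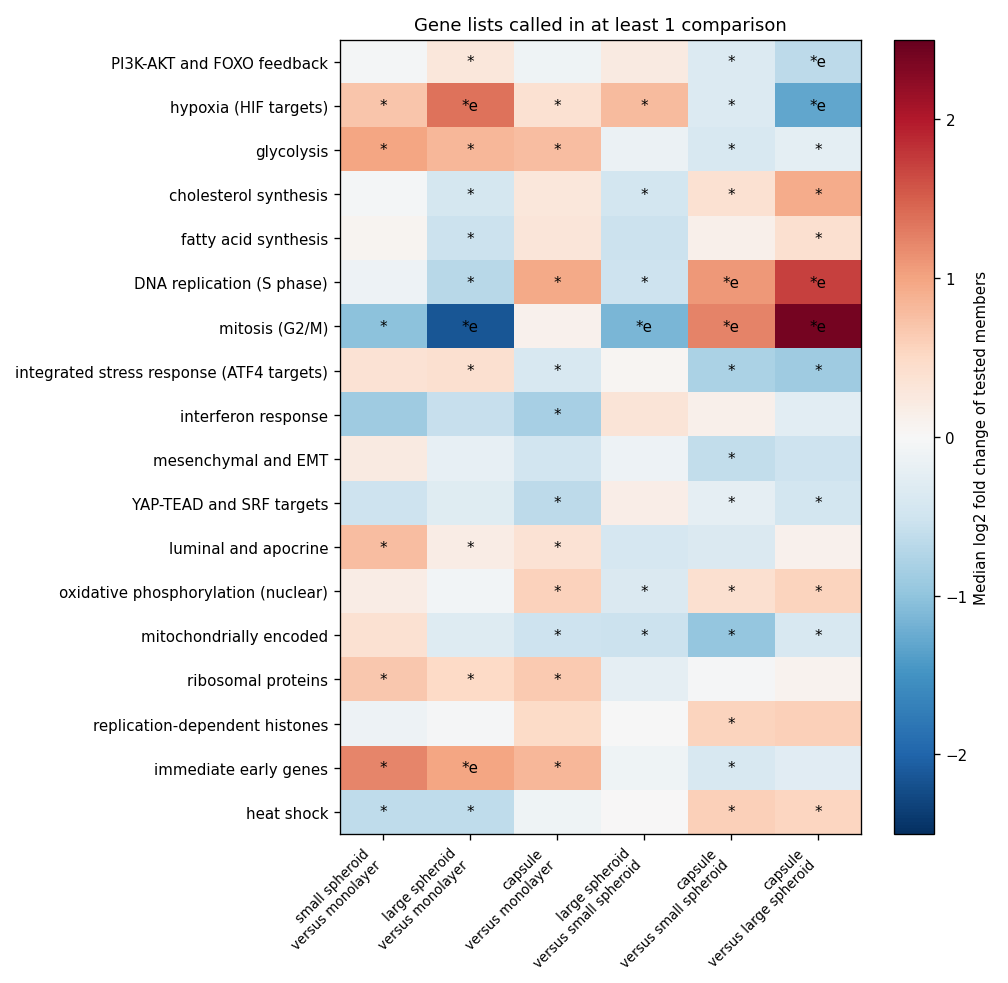
Median log2 fold change of the tested members of each gene list called in at least 1 comparison, by comparison, red for higher and blue for lower in the first format. An asterisk marks a camera call with the preset correlation and the letter e a call with an estimated correlation, which 10 of the 62 calls kept.

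The other 14 lists were called in no comparison with the preset correlation, though camera under other settings called 4 of them. MHC presentation in capsule against monolayer was called under limma-voom (adjusted p = 0.028), the replicate block (0.0491), the GC and length correction (0.00752) and without monolayer replicate 3 (0.029). Fibroblast markers in the same comparison were called without monolayer replicate 3 (adjusted p = 0.029), and the ERBB list in small spheroid against monolayer under limma-voom (0.0423). Epithelial junctions were called under the correction in large against small spheroid (adjusted p = 0.000166) and in capsule against large spheroid (0.0461). The lowest and highest adjusted p over the 6 comparisons were 0.121 and 0.978 for ERBB receptors, ligands and the 17q12 amplicon, 0.609 and 0.987 for the unfolded protein response, 0.289 and 0.987 for p53 targets and 0.0643 and 0.987 for MHC presentation. They were 0.121 and 0.987 for NF-kB and cytokines, 0.101 and 0.861 for epithelial junctions and keratins, 0.166 and 0.987 for integrins and basement membrane, and 0.442 and 0.987 for basal and myoepithelial genes. Stem-like markers gave 0.176 and 0.987, drug transporters 0.566 and 0.986 and NRF2 targets 0.79 and 0.994. Of cell types, fibroblast markers gave 0.199 and 0.987, endothelial markers 0.609 and 0.986 and leukocyte markers 0.336 and 0.994. Median and test differed in sign for some of these: NRF2 targets in capsule against monolayer had a median of 0.45 with a test pointing down, and fibroblast markers in large against small spheroid a median of 1 with a test pointing down. Fibroblast markers in capsule against small spheroid had a median of 0.13, or -0.08 with POSTN at its bound.

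**Figure D4:**
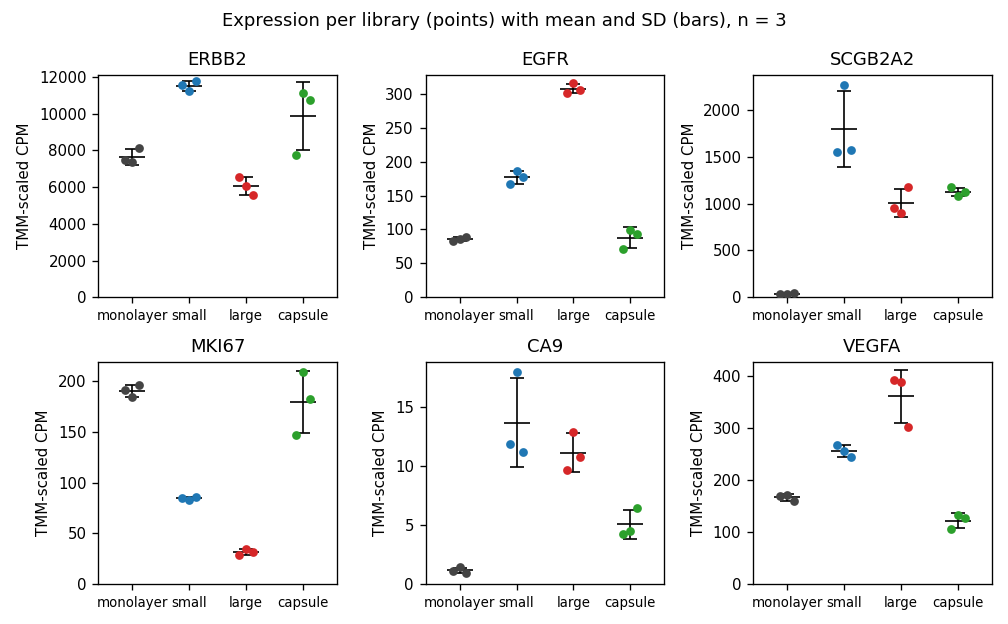
TMM-scaled CPM of ERBB2, EGFR, SCGB2A2, MKI67, CA9 and VEGFA per library, with points for the 3 libraries of each format and bars for mean and SD. MKI67 has its lowest mean in large spheroids at 31.8 CPM, where EGFR and VEGFA have their highest at 307.8 and 361.3 CPM.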

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

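The tests of the library titles and of the bias as the whole cause of the split were chosen after the result was seen, and the correction for GC content and transcript length was chosen after seeing the data.

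DNA replication genes moved in opposite directions against monolayer, down in large spheroids and up in capsules, calls that were both lost with an estimated correlation (adjusted p = 0.0681 and adjusted p = 0.088). The difference itself, capsule against large spheroid, had a median log2 fold change of 1.70 (adjusted p = 7.17e-25, and adjusted p = 0.00106 with an estimated correlation). Targets of ATF4 did the reverse, up in large spheroids and down in capsules, calls also lost with an estimated correlation (adjusted p = 0.32 and adjusted p = 0.533). They had a median of -0.90 between them (adjusted p = 3.6e-09, and adjusted p = 0.0854 with an estimated correlation). Both differences were picked out because the formats differed in sign under the same contrast.

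Regrouping tested whether the calls could arise from a random assignment of these libraries to formats. Over all 4 formats the real grouping called 13654 genes and the highest other grouping 1488. Of the 50 groupings 1, the real one itself, called as many, so a random assignment is excluded. Chance differences between cultures are not excluded, because the replicates of a format may not be separate cultures. For pairs of formats the 10 splits of 6 libraries are too few for a share under 0.05. Fitted on the 2 formats alone, small spheroid against monolayer called 11320 genes with 0 in the highest other split. The real values were 9474 for large spheroid and 9165 for capsule against monolayer, 10467 for large against small spheroid, 6856 for capsule against small spheroid and 8404 for capsule against large spheroid. In each of these 1 split, the real one, called as many and the highest other split called 0.

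The first principal component set small spheroid and capsule libraries against monolayer and large spheroid libraries, and fold changes between these sides followed GC content (Spearman rho 0.614) and transcript length (-0.325). After the correction 7287 (66%) of the 11047 genes called before were still called in the same direction, short of the bound set for excluding the bias, so its share stays open. The corrected first component (38.2% of the variance) still set the same libraries apart. The smallest gap between the sides was 50.2 and the largest range within a format 8.34. The part of the bias that this correction models is therefore excluded as the whole cause of the split. Bias that the correction does not model could remain. A separate preparation or run of the libraries with UP in their titles stays open too, because titles and formats are confounded: the comparisons that cross the titles called at least 9511 genes, and those within a kind of title 8669 and 7892. The biological difference between formats is the third open explanation, and it cannot be told apart from a preparation or run here.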

How the results depend on the processing

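The GC and length correction was chosen after seeing the data, and the other alternatives before. The numbers of called genes stayed within 1.5 times their values under every alternative except the 2-fold threshold, which by its construction left 4637 genes for small spheroid, 2674 for large spheroid and 3411 for capsule against monolayer, 3005 for large against small spheroid, 1498 for capsule against small spheroid, 3205 for capsule against large spheroid, 7682 for any difference and 886 in the same direction in all 3 formats. The 62 list calls became 10 with an estimated correlation between genes, 137 with fry in 1 direction and 191 with fry in either, because these tests ask other questions or assume other correlations. Apart from the 2-fold threshold, and with single libraries left out counted below, the lowest and highest counts were 9516 and 11320 for small spheroid, 6890 and 9474 for large spheroid and 8419 and 10264 for capsule against monolayer. They were 8003 and 10467 for large against small spheroid, 5958 and 8022 for capsule against small spheroid and 7749 and 9817 for capsule against large spheroid.

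Leaving out 1 library at a time gave 10360 to 10668 genes for small spheroid, 7715 to 8235 for large spheroid and 9285 to 10704 for capsule against monolayer. It gave 9296 to 9637 for large against small spheroid, 6836 to 7869 for capsule against small spheroid and 8630 to 10133 for capsule against large spheroid. Any difference ranged from 13513 to 13937, genes in the same direction in all 3 formats from 3821 to 5288 and list calls from 61 to 68. The highest values of capsule against monolayer, capsule against large spheroid and the shared direction came without capsule replicate 1. With the replicate number as a block the counts were 10833, 8399, 9848, 9873, 7576 and 9296 in the order above, and 64 lists were called. By the rule that every pair must pass 0.1 the numbers do not pair the samples: 2 of 18 residual correlations between libraries of the same number passed it, with a range of -0.215 to 0.217. Both were between monolayer and large spheroid, where the same-number values were 0.0895, 0.154 and 0.217 and the others ran from -0.188 to 0.0856, and 6 of 12 libraries correlated best with their own number. Pairing by number between some formats is therefore not excluded. Of genes chosen after their values were seen, MYH6 stood at 0 CPM in replicate 3 of monolayer and of large spheroids, unlike their other replicates. SNORD3A stood at 48.43 and 57.37 CPM in replicate 3 of small spheroids and of capsules, and no higher than 5.563 in their other replicates.

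Of the 280 calls of named genes, 263 kept direction and call under every alternative and 271 under every one set before the data were examined. The reversals all came with the GC and length correction, and the cause was not tested. GRB7 turned to -0.22 in small spheroid and -0.44 in capsule against monolayer and to 0.092 in large against small spheroid. FASN turned to -0.88 in small spheroid and -0.11 in capsule against monolayer, and MKI67 to 0.23 in capsule against monolayer. The glycolysis list turned to 0.19 in large against small spheroid. The correction called 73 lists in place of 62.

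With 3 libraries per format and unknown independence between them, the calls measure the spread between these libraries alone. Thinning all libraries to the smallest total ended 1 list call and no call of a named gene. Depth limits genes with few counts, such as CDH1 with 2 and 3 counts in capsules and small spheroids, too few to detect a difference.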

Other observations

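The tests of depth, of 1 source and of a format effect below were chosen after the result was seen, and so were the genes named here.

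Some genes outside the lists' calls changed in all 3 formats against monolayer. The organic anion transporter SLCO4A1 rose from 3.90 ± 0.79 to 62 ± 5.9 CPM in small spheroids, 31.3 ± 3.3 in large spheroids and 39 ± 1.4 in capsules (SD, n = 3). NOTCH3 rose from 100.2 ± 7 to 418.2 ± 25.7, 179.5 ± 15 and 240.6 ± 54.9 CPM, and its target HEY1 by log2 fold changes of 1.92, 2.46 and 1.08. The stem cell marker PROM1 fell from 115.1 ± 3.3 to 30.1 ± 1, 38.2 ± 2.2 and 19.7 ± 2.2 CPM, and the transporter ABCC11 from 32.4 ± 3.1 to 10.2 ± 0.64, 6.62 ± 0.84 and 5.38 ± 0.09. The drug efflux gene ABCG2 fell in both spheroid formats (-1.25 and -1.14) and rose in capsules (1.58). The ferritin gene FTH1 rose from 326.6 ± 62.8 to 828.8 ± 42.9, 1255 ± 110 and 465.3 ± 22.4 CPM, whereas FTL rose in small (0.43) and large spheroids (0.81) and fell in capsules (-1.05).

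Capsule replicate 1 lay apart from capsule replicates 2 and 3, and its column in the count table, assigned by format and number, names the format in another spelling than theirs. Its deviation followed the difference to monolayer with a Pearson r of 0.311, to large spheroids with 0.185 and to small spheroids with -0.134. These values lie below the bound of 0.5 set for excluding RNA of another format mixed into it. A small share of such RNA is not excluded, because a deviation that also follows GC content can hold r low. A difference in depth is excluded, as its total was at most 1.11 times that of another capsule library. A GC content bias of that library remains a candidate explanation, since its deviation followed GC content across genes with a Spearman rho of -0.578. No biological explanation was tested.

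Some melanocyte, stromal and cardiac genes, among them TYRP1, POSTN and MYH6, were higher in most monolayer and large spheroid libraries than in the others, while MB, HSPB7 and TTN were read in all 12. A set of 59 genes was chosen for mean CPM under 0.2 in small spheroids and in capsules and at least 1 in monolayer. It held POSTN and CDH1. The set's median absolute log2 ratio of monolayer 3 to the mean of monolayer 1 and 2 was 1.41, above the highest of 1000 random sets (0.422). This argues against a format effect acting alike on the monolayer cultures as the only cause. Such an effect beside another cause is not excluded, and genes of the set may move together, unlike those of random sets. A single source in 1 fixed mixture is excluded, since the ratio of monolayer 3 to the mean of monolayer 1 and 2 had a median of 0.000533 (interquartile range 0 to 0.00722) for the 4 cardiac genes of the set and 0.394 (0.316 to 0.66) for the rest. RNA or reads of other cells in single libraries remains a candidate explanation. Of 30 cardiac genes listed and 19 in the table, 14 had not been looked at before. Of these, 10 had their 2 highest CPM in monolayer 1 and 2.

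The melanocyte list, with 14 of 20 genes in the table, was used only to look at values such as those of TYRP1, and no test was run on it. The hepatocyte list, with 14 of 25 genes in the table, was likewise not tested. Some of its genes went the other way: LPA stood at 0 to 0.174 CPM in monolayer and large spheroid libraries and at 0.859 to 3.675 in the others, and APOA1 at 0 to 0.118 and at 0.859 to 5.526. FGG stood at 775.7 to 842.7 CPM in capsules, 396.4 to 497.5 in small spheroids, 167.1 to 178.7 in monolayer and 130.7 to 184.8 in large spheroids.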
